A study of Mus musculus with 6 samples.

How the data were processed

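Gene expression was measured by RNA sequencing of muscle labelled quadriceps from 20-week-old C57BL/6 mice, 3 WT and 3 muscle-specific Esr1 knockout libraries. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit, which does not mark strand, and per the series' design text they were sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, TopHat 1.3.3, edgeR and the mouse genome build mm10 were used, with no role or order given. The read counter, the annotation release and the treatment of reads that map to several places are not given in the sources used here. The authors' deposited table holds whole-number counts per Ensembl gene for each of the 6 libraries, not normalized. It also holds a log2 fold change and a log2 mean abundance that the authors computed, with a p-value and an adjusted p-value deposited for each gene; per the file headers these carry the column names of edgeR. The scaling and the test behind them are not given in the sources used here. The adjusted p-values deposited by the authors matched a Benjamini-Hochberg adjustment over all 37477 Ensembl IDs.

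The table had 37506 rows, of which 29 repeated an Ensembl ID with identical counts and were merged. Of the 37477 IDs 30200 had a symbol in the table and 3232 took one from GENCODE M21, whose assembly GRCm38 is the one mm10 names; 32608 IDs matched that release, which gave coordinates and exonic lengths. No row stood for unassigned reads. IDs without a match to that release held 10.2% ± 0.557 (SD, n = 3) of WT and 10.6% ± 0.643 (SD, n = 3) of KO counts, mostly in 2 IDs without a symbol. In all, 13524 IDs had no counts. Because the counting of multi-mapped reads is not known and strand was not kept, counts of near-identical copies such as Hba-a1 and Hba-a2, of 7SK copies and of overlapping genes are uncertain. The gene Tnnc1 had 0 counts in 5 libraries and 1 in the other, and no value is drawn from it.

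Total counts ranged from 7388365 to 8560244 per library. Pairs of replicates differed by more than sampling noise in every case (chi-square per gene of 3.46 to 9.57, over genes with a pair sum of at least 10). This goes against the same library having been sequenced again, and all 6 libraries were counted as separate. It cannot tell whether they came from separate animals or RNA samples.

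Differential expression was tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, which kept 13848, scaled with TMM (factors 0.968 to 1.037), and tested two-sided with the robust quasi-likelihood F-test (glmQLFit and glmQLFTest) on genotype alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F, and 95% intervals used the test's degrees of freedom. CPM values use the TMM-scaled library sizes. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, for the 34 of 38 lists with at least 5 measured members, adjusted over those lists; camera with an estimated correlation and fry were alternatives. The 4 myosin heavy chain shares were compared by exact two-sided permutation tests of the difference in means, which cannot go below 0.1 with 3 against 3 libraries; other single values were compared by their spread.

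The design, the lists and the rule for named genes were fixed before the data were examined. Named were Esr1, then the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between groups. As none qualified, the 5 genes with the smallest unadjusted p in each direction took their place, given as values that did not pass. Then came up to 4 members of each list with the smallest unadjusted p, and always Polg, Tfam, Rcan1, Dnm1l, Park2, Ppargc1a, Esr2, Esrra and Gper1. Predicted genes without a symbol and antigen receptor segments were counted but not named, except where stated.

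The alternatives set beforehand were RLE, upper-quartile and no scaling, no filter beyond 1 read, a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a replicate block, leaving out each library, RLE, fry and an estimated correlation for the lists, and a threshold of 0.01 for the authors' comparison. Alternatives that apply only to normalized values were not run, since the values are counts. Chosen after seeing the data were edgeR's exact test and likelihood ratio test, edgeR's newer quasi-likelihood fit, removal of 7SK and 7SL rows, the receptor list without Esr1, a list test corrected for gene length, and the permutation tests of the myosin shares. Tables and figures were made with Python 3, pandas and matplotlib.

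The test was tested on simulated data in 5 runs. Counts for the 13848 genes were drawn from the means and library sizes of these libraries. The spread of each gene (its dispersion) was the one the fit had estimated, and genes were drawn independently. In each run 200 genes of at least 5 CPM were changed by known folds. For KO against WT, 59.6% of genes changed 1.5-fold were called, 96.8% at 2-fold, 98.4% at 3-fold and 100% at 4-fold. In that order these were 149, 242, 246 and 250 calls over the 5 runs. Another 97 calls were false, a larger share of all calls than the threshold of 0.05 aims at. With 12 changed genes in each of 10 runs, 90% of those changed 2-fold were called and 100% at 3-fold. No structure shared between libraries was simulated, so these shares can be too high for the real libraries. There Actn3, at 2.60 times the WT level, had an adjusted p of 0.989 in the quasi-likelihood test.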

Results

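RNA was measured in muscle labelled quadriceps, the large muscle group at the front of the thigh, of 20-week-old C57BL/6 mice of 2 genotypes. Wild-type (WT) mice were set against MERKO mice, in which the estrogen receptor alpha gene had been knocked out in muscle only; these are called KO here. Each group held 3 libraries. The labels do not say whether each library came from 1 animal, so p-values measure the spread between these libraries. Total counts were 7733401, 7388365 and 7728795 in WT replicates 1, 2 and 3, and 8560244, 8376466 and 7809612 in KO replicates 1, 2 and 3. At this depth 20066.7 ± 103.7 genes (SD, n = 3) had at least 1 count in WT and 20173.7 ± 70.4 (SD, n = 3) in KO. Ttn, which encodes the giant sarcomere protein titin, took 15.6% ± 1.09 (SD, n = 3) of WT counts and 14.1% ± 0.743 (SD, n = 3) of KO counts. Genes of the mitochondrial genome took 7.22% ± 0.260 (SD, n = 3) in WT and 7.57% ± 1.75 (SD, n = 3) in KO, where replicate 1 reached 9.53%. Xist, the RNA that coats the inactive X chromosome of female cells, had 1398 to 1553 counts per library, and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in all 6, where 0 allows up to 3 counts. This limit covers counting error only.

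The first comparison asked whether the knocked-out gene was lower in the libraries labelled KO. Esr1 (ENSMUSG00000019768), which encodes estrogen receptor alpha, lies on chromosome 10 from 4611593 to 5005614 on the plus strand in mm10. Its counts were 50, 41 and 44 in WT replicates 1, 2 and 3 and 22, 16 and 16 in KO replicates 1, 2 and 3. Mean abundance was 5.96 ± 0.638 CPM (SD, n = 3) in WT and 2.17 ± 0.374 CPM (SD, n = 3) in KO, 0.367 times the WT level, and all 3 KO values lay below all 3 WT values. The log2 difference of KO from WT was -1.45 ± 0.23 (SE), with a 95% interval from -1.94 to -0.95. In edgeR's quasi-likelihood test Esr1 had the smallest p of all genes, 1.04e-05, and an adjusted p of 0.145 over the 13848 genes tested, which did not pass 0.05. Adjusted over the list alone, among 25 measured receptors and coregulators, its p was 0.000261. Counts were summed over the gene, so the KO value can hold reads from cells other than muscle fibres and from exons outside the deleted part. That part is not given in the sources used here, and the origin of the KO reads was not tested. Esr1 passed over all genes without the filter on low counts (adjusted p = 0.000142) and, in tests chosen after seeing the data, in edgeR's exact test (4.83e-05) and likelihood ratio test (0.000116).

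**Figure D1:**
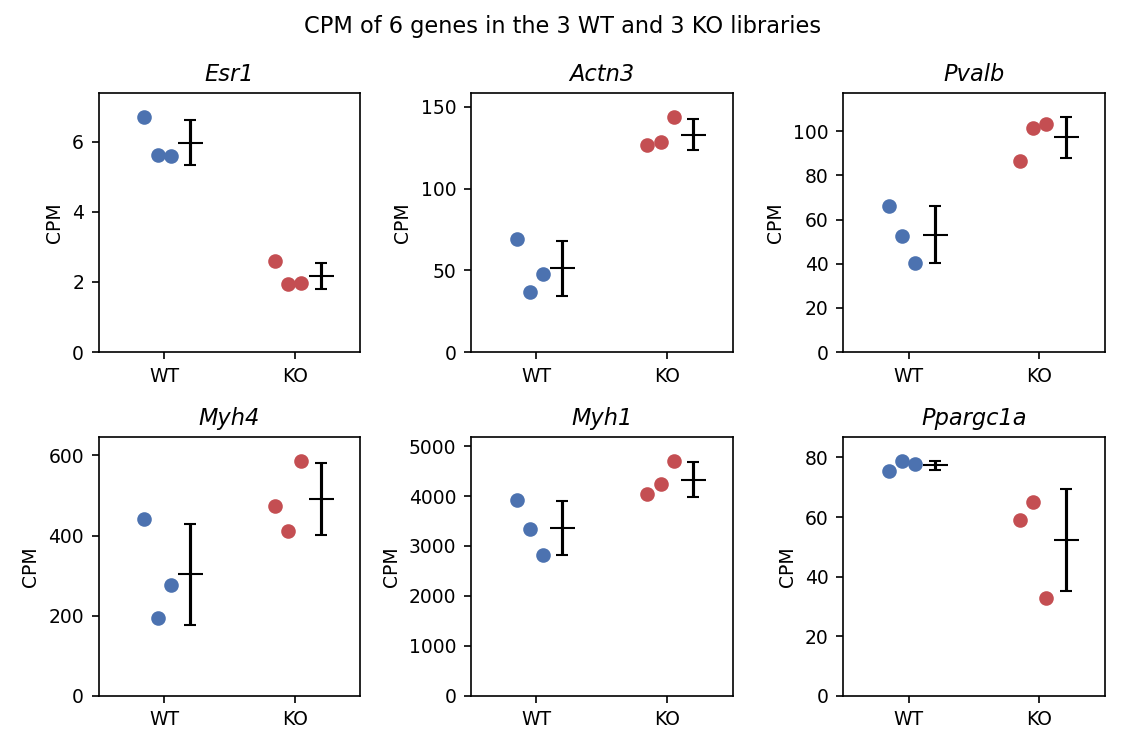
CPM (vertical axes, each from 0) of Esr1, Actn3, Pvalb, Myh4, Myh1 and Ppargc1a in the 3 WT and the 3 KO libraries; points are libraries and the bars beside them show the mean and SD of each group. Esr1 lay below 3 CPM in all KO libraries and above 5 CPM in all WT libraries, Actn3 was at 126 to 144 CPM in KO and 36.5 to 69.4 CPM in WT, and Myh4 overlapped between the groups.

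Across the transcriptome, few differences between the 2 genotypes stood out from the spread between libraries. Another split, WT replicates 1 and 2 and KO replicate 2 against the rest, called 96 genes. Such structure apart from genotype widens the spread within each group, so missing calls do not by themselves show that the genotypes were alike. No gene rose or fell in KO at an adjusted p under 0.05 in edgeR's quasi-likelihood test: 0 were higher and 0 were lower of 13848 tested. At an unadjusted p under 0.05 there were 590 genes, 276 higher and 314 lower, where chance alone gives 692. The groups did not overlap for 687 genes with all KO values above WT and 755 with all below, 10.4% of genes, where chance gives 10%. Among genes with a symbol, those with the smallest p that were higher in KO, none of which passed, were led by Cib2, a calcium- and integrin-binding protein, at 3.26 ± 0.250 CPM (SD, n = 3) against 1.28 ± 0.194 in WT, and by Rps3a, a protein of the small ribosomal subunit, at 87.9 ± 6.81 CPM against 65.5 ± 7.25. They were followed by Lin7a, a scaffold protein of cell junctions, with a log2 difference of 0.98, Pvalb with 0.87 and Myoz1 with 0.31. On the lower side, again among genes with a symbol and after Esr1, stood the zinc-finger gene Zfp646 (log2 difference -0.45), the cell-death gene Bmf (-0.76), Pln, the inhibitor of the slow-fibre calcium pump (-0.43), and the calcium channel subunit Cacnb4 (-1.27). After Esr1 the lowest adjusted p of any gene was 0.98. The median half-width of the 95% interval was 0.265 log2 units among the 10005 genes of at least 5 CPM, and for 9840 of these the interval lay within a 2-fold change either way. DESeq2 called 3 genes, limma voom called 0, and edgeR without the filter on low counts called 19, 14 of them higher and 5 lower. Among the higher ones, Rnu2-10 and several predicted genes had near-identical log2 differences of 0.39 and the same adjusted p (0.022). These may not be separate signals. Without WT replicate 1 the quasi-likelihood test called 3 genes, Actn3, Pvalb and Gm23624.

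The authors' deposited table also holds their own comparison, which called 5 genes at an adjusted p under 0.05, 3 higher and 2 lower in KO. In the authors' deposited table Actn3, the alpha-actinin of fast fibres, had a log2 fold change of 1.39 with an adjusted p of 4.67e-11, and Pvalb, the calcium buffer parvalbumin of fast fibres, had 0.89 with 3.71e-05. Esr1 had -1.43 with an adjusted p of 0.000152 in the authors' deposited table. The other 2 genes of the authors' deposited table were Gm23624, a copy of the small nuclear RNA 7SK, at -4.48, and ENSMUSG00000091658, with no symbol, at 1.40; both are named because the table holds so few. Gm23624 had 1, 37 and 70 counts in WT replicates 1, 2 and 3 and 2, 2 and 1 in KO, so that its difference rested on 2 WT libraries, and it was 1 of 331 genes annotated as 7SK, so that its counts are uncertain where reads map to several copies. Gm23624 was removed by the filter on low counts and so was not tested in the quasi-likelihood fit. None of the other 4 genes passed there, where Actn3 had an adjusted p of 0.989 and Pvalb 0.989. Across the 13848 genes tested, log2 fold changes from the authors' deposited table and from the quasi-likelihood fit had a Pearson r of 0.9999 as a description across genes, which are not independent replicates.

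Gene groups were compared next, with 38 lists of which 34 had at least 5 measured members. Camera, which tests a list against all other genes, placed 8 lists past an adjusted p of 0.05, 6 higher and 2 lower in KO, while no list member was called over all genes. Each of the 8 calls was made with a preset correlation between genes of 0.01. None held with an estimated correlation, where the lowest adjusted p of any list was 0.318.

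The fast-twitch contractile genes had the smallest camera p of the 34 lists, though not the largest median difference. Of 16 measured members 13 were higher and 3 lower in KO, with a median log2 difference of 0.12 and a camera adjusted p of 3.26e-09 (adjusted p = 0.318 with an estimated correlation). Over all genes 0 were called. Adjusted over the list alone, 4 members were higher and 0 lower: Actn3, Pvalb, Myoz1 and Myh1. Actn3 was at 51.1 ± 16.7 CPM in WT and 133 ± 9.43 CPM in KO (SD, n = 3 each), 2.60 times the WT level with a 95% interval of the log2 difference from 0.77 to 1.99. Pvalb was at 53.1 ± 12.9 CPM in WT and 97.2 ± 9.21 CPM in KO (SD, n = 3 each). Myoz1, which ties calcineurin to the Z-disc of fast fibres, was at 110 ± 8.44 and 136 ± 8.71 CPM, and Myh1, the myosin heavy chain of type IIX fibres, at 3363 ± 547 and 4329 ± 347 CPM (SD, n = 3 each). All 3 KO values lay above all 3 WT values for each of these 4 genes. Over all genes Actn3 and Pvalb passed in DESeq2 (adjusted p = 0.0059 and 0.000128), in edgeR's exact test (7.92e-11 and 5.13e-05) and likelihood ratio test (0.000208 and 0.00452), and without WT replicate 1 (4.96e-05 and 0.00633). Without the filter on low counts Pvalb (3.38e-17) and Myh1 (0.00132) passed and Actn3 did not. The highest adjusted p over the 18 alternatives was 0.9997 for both Actn3 and Pvalb. The log2 differences of the other 12 members, none of which passed, ran from -0.15 for Myh2 to 0.69 for Myh4, both named after their values were seen. The slow-twitch contractile genes did not pass (7 higher and 6 lower, adjusted p = 0.639); Tnni1, the slow troponin I, was at 1309 ± 104 CPM in WT and 1472 ± 76.4 CPM in KO (SD, n = 3 each). The slow-twitch list passed as higher without WT replicate 2 (camera adjusted p = 0.0246). That value assumes the preset correlation of 0.01, while the estimated correlation over all libraries was 0.4235.

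**Figure D2:**
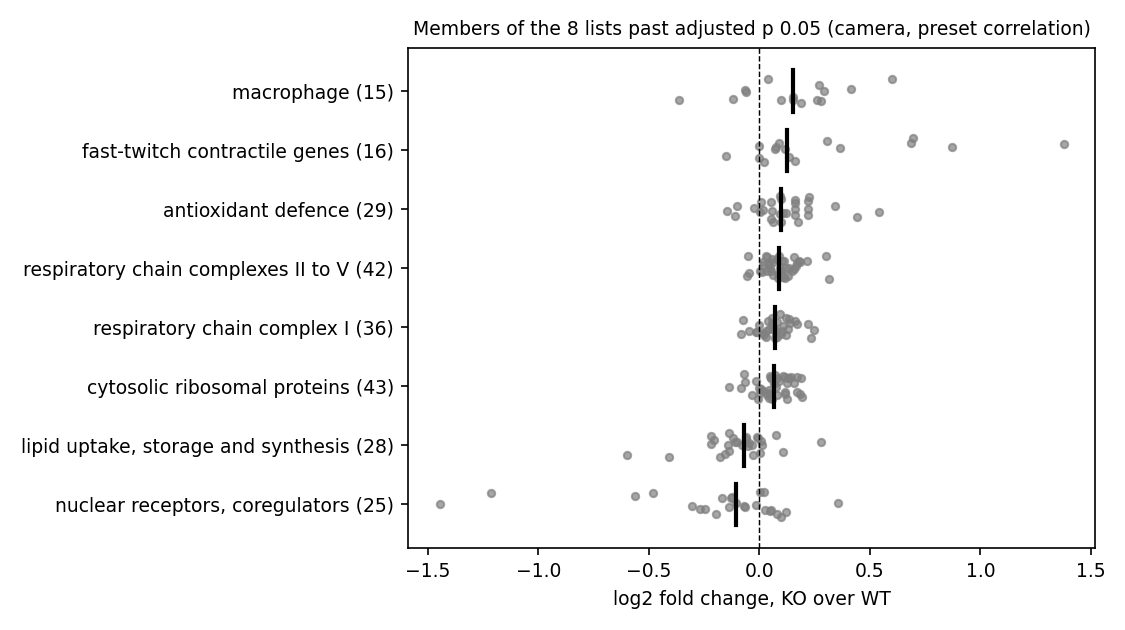
Log2 fold change of KO over WT (horizontal axis) for each measured member of the 8 lists past the camera threshold, with the number of members in parentheses; points are genes, spread vertically at random, and black bars are medians. Most members lay within 0.5 log2 units of 0, and Esr1 at -1.45 and Actn3 at 1.38 lay farthest out.

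Muscle fibre types were read from the myosin heavy chains, of which slow-fibre forms took most counts in both genotypes. Of the counts of the 4 adult myosin heavy chains, Myh7 of slow type I fibres took 60.6% ± 2.39 (SD, n = 3) in WT and 59.7% ± 1.11 in KO, and Myh2 of type IIA fibres 29.2% ± 2.90 and 26.6% ± 1.79. Myh1 of type IIX fibres took 9.36% ± 0.796 in WT and 12.3% ± 0.593 in KO, and Myh4 of type IIB fibres 0.844% ± 0.315 and 1.39% ± 0.200 (SD, n = 3 each). The slow calcium pump gene Atp2a2 had 2.82 ± 0.172 times the counts of the fast Atp2a1 in WT and 2.59 ± 0.186 times in KO. Exons of other genes overlap 21.9% of the exonic bases of Atp2a1. The slow light chain gene Myl2 had 4.57 ± 0.232 times the counts of the fast Mylpf in WT and 4.21 ± 0.259 times in KO. The slow troponin gene Tnni1 went the other way, at 0.79 ± 0.059 times the counts of the fast Tnni2 in WT and 0.85 ± 0.029 times in KO (SD, n = 3 each). These are ratios of counts, not corrected for gene length. Groups overlapped for the Myh7 and Myh2 shares, and all KO values lay above all WT values for the Myh1 and Myh4 shares. In exact two-sided permutation tests, chosen after seeing the data, the Myh1 and Myh4 shares each had a p of 0.1, the smallest that 3 against 3 libraries allow, the Myh2 share 0.5 and the Myh7 share 0.6. Adjusted over the 4 shares these were 0.2, 0.2, 0.6 and 0.6.

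**Figure D3:**
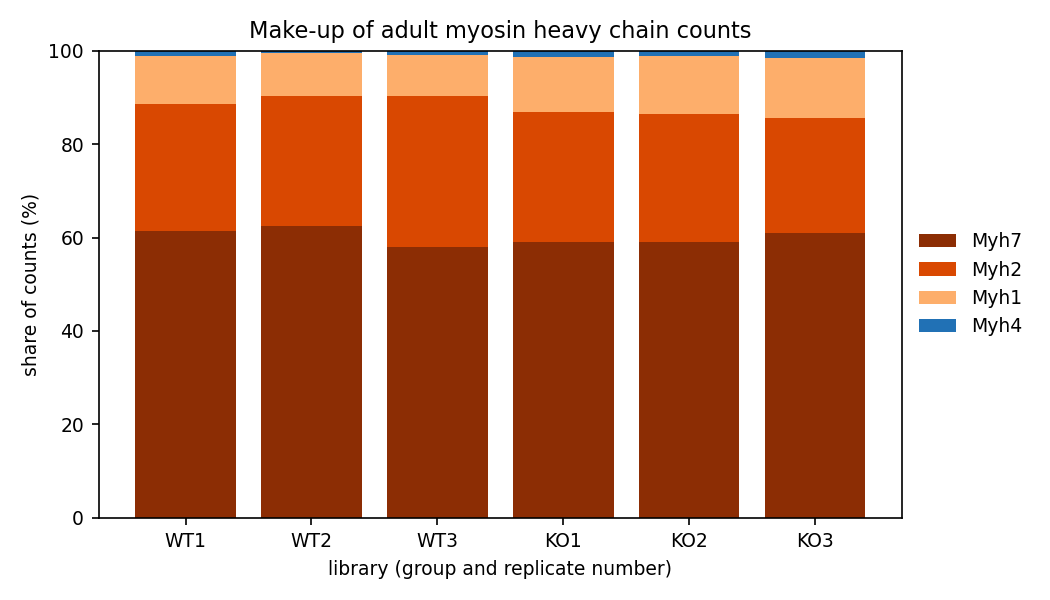
Share of the counts of 4 adult myosin heavy chain genes (vertical axis, percent) in each of the 3 WT and 3 KO libraries (horizontal axis); each bar adds up to 100%. Myh7 took the largest part of every bar, and Myh4 between 0.525% and 1.60%.

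Nuclear genes of the respiratory chain were slightly higher in KO. Of 42 members of complexes II to V 39 were higher and 3 lower, with a median log2 difference of 0.09 and a camera adjusted p of 9.64e-06 (adjusted p = 0.431 with an estimated correlation). Of 36 members of complex I 31 were higher and 5 lower, with a median of 0.07 and an adjusted p of 0.000552 (adjusted p = 0.431 with an estimated correlation). No member was called over all genes or adjusted over the list alone. The ATP synthase subunit Atp5e was at 162 ± 0.667 CPM in WT and 200 ± 30.1 CPM in KO, Uqcr11 of complex III at 52.8 ± 2.42 and 61.4 ± 4.80 CPM, and Ndufb6 of complex I at 53.4 ± 2.45 and 62.8 ± 6.39 CPM (SD, n = 3 each). The 15 genes of the mitochondrial genome itself did not pass (10 higher and 5 lower, median 0.01, mean 0.00, adjusted p = 0.937), and mt-Co1 was at 36190 ± 1479 CPM in WT and 38140 ± 10500 CPM in KO. The direction of this list turned with single libraries: without KO replicate 1 it was lower (adjusted p = 8.79e-09), and without KO replicate 3 it was higher (0.00031). Both values came from camera at the preset correlation of 0.01. The estimated correlation of this list over all libraries was 0.885, so that both p-values can be far too small. Log2 fold changes also varied with transcript length: the Spearman correlation of log2 fold change with exonic length was -0.186 across 13220 genes, which are not independent replicates. A test on signed z values of the genes, chosen after seeing the data, corrected for length and abundance. It moved complex I from a mean z of 0.852 to 0.519 (adjusted p from 6.0e-05 to 0.0345). Complexes II to V moved from 1.03 to 0.682 (adjusted p from 2.13e-07 to 0.00149).

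Genes that copy, transcribe, divide and clear mitochondria did not pass as groups. Mitochondrial DNA replication and transcription had 14 members higher and 12 lower (adjusted p = 0.939). Polg, the mitochondrial DNA polymerase, was at 45.5 ± 3.75 CPM in WT and 47.6 ± 1.87 CPM in KO, and Tfam, which packages mitochondrial DNA, at 42.1 ± 1.36 and 40.1 ± 1.59 CPM (SD, n = 3 each). The 95% intervals of their log2 differences ran from -0.12 to 0.25 and from -0.25 to 0.11. Fission and fusion had 10 members higher and 10 lower (adjusted p = 0.978), and the fission enzyme Dnm1l was at 98.9 ± 0.615 CPM in WT and 93.6 ± 10.4 CPM in KO. Mitophagy and autophagy had 21 higher and 15 lower (adjusted p = 0.209). Park2, the ubiquitin ligase parkin, was at 4.64 ± 0.660 CPM in WT and 6.50 ± 0.398 CPM in KO, with all KO values above WT. Its unadjusted p of 0.0221 in the quasi-likelihood test did not pass (adjusted p = 0.989). Another ID with this symbol, ENSMUSG00000073465, had 7, 5 and 3 counts in the WT libraries and 4, 6 and 4 in the KO libraries, which overlapped. The calcineurin pathway had 8 higher and 14 lower (adjusted p = 0.679). Its inhibitor Rcan1 was at 119 ± 2.25 CPM in WT and 138 ± 8.72 CPM in KO with all KO values above WT, an unadjusted p of 0.0097 and an adjusted p of 0.989. Myoz1 was the 1 member of this pathway that passed adjusted over the list alone.

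Antioxidant genes stood higher as a group, 25 higher and 4 lower of 29, with a median log2 difference of 0.10 and a camera adjusted p of 0.000552 (adjusted p = 0.318 with an estimated correlation). The peroxidase Gpx8 differed by a log2 value of 0.54 ± 0.16 (SE), and the peroxiredoxin Prdx1 was at 45.5 ± 1.33 and 53.0 ± 3.21 CPM (SD, n = 3 each). Cytosolic ribosomal proteins had 35 members higher and 8 lower, a median of 0.07 and an adjusted p of 0.0073 (adjusted p = 0.681 with an estimated correlation); Rpl22 was at 53.6 ± 5.66 and 60.2 ± 5.19 CPM. Macrophage markers had 11 higher and 4 lower of 15, with a median of 0.15 and an adjusted p of 0.0182 (adjusted p = 0.652 with an estimated correlation), and the mannose receptor gene Mrc1 was at 21.1 ± 5.30 and 28.1 ± 1.27 CPM. In none of the 3 lists was a member called, over all genes or adjusted over the list alone. Single libraries decided part of this: the antioxidant call ended without KO replicate 1 (adjusted p = 0.056). The ribosomal call ended without WT replicate 3 (0.201), KO replicate 2 (0.327) or KO replicate 3 (0.0857), and the macrophage call without WT replicate 2 (0.614) or KO replicate 2 (0.281), all as camera adjusted p. In a test on signed z values of the genes, chosen after seeing the data, correction for gene length and abundance moved the macrophage list from an adjusted p of 0.0332 to 0.0505, with a mean z of 0.708 ± 0.923 before and 0.652 ± 0.949 after (SD over 15 genes). It moved the ribosomal list from 0.00234 to 0.0868, with a mean z of 0.625 ± 0.75 before and 0.385 ± 0.727 after (SD over 43 genes).

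Nuclear receptors and their coregulators stood lower as a group. Of 25 measured members 9 were higher and 16 lower, with a median log2 difference of -0.10 and a camera adjusted p of 0.000552 (adjusted p = 0.431 with an estimated correlation). The list contains Esr1 itself, and with Esr1 left out, an alternative chosen after seeing the data, the adjusted p was 0.0182. Esr1 was the 1 member lower when adjusted over the list alone. The members had a median exonic length of 6047 bases, against 4184 over the genes tested. The test on signed z values, chosen after seeing the data, corrected for length and abundance. It moved this list from a mean z of -0.758 to -0.616 (adjusted p from 0.00381 to 0.0282), so that length may carry part or all of its fall. Nr4a3, an orphan receptor induced by activity, was at 1.98 ± 0.451 CPM in WT and 0.847 ± 0.209 CPM in KO, and the corepressor Ncor1 at 142 ± 5.46 and 125 ± 5.87 CPM (SD, n = 3 each). The mitochondrial coactivator Ppargc1b was at 7.30 ± 1.12 and 5.24 ± 0.311 CPM. Its relative Ppargc1a was at 77.3 ± 1.64 CPM in WT and 52.3 ± 17.2 CPM in KO, with all KO values below WT, a log2 difference of -0.56 and an adjusted p of 0.989. With 1 library left out, the log2 difference of Ppargc1a ran from -0.75 to -0.32. Esrra, the estrogen-related receptor alpha gene, was at 127 ± 8.33 and 129 ± 11.5 CPM. Gper1, the membrane estrogen receptor, listed under its older name Gpr30, was at 1.98 ± 0.590 and 2.54 ± 0.532 CPM. Esr2, which encodes estrogen receptor beta, had 0 counts in all 6 libraries, where 0 allows up to 3 counts. The separate list of estrogen-responsive genes did not pass (11 higher and 6 lower, adjusted p = 0.947).

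Genes of lipid uptake, storage and synthesis were the other group that stood lower, 22 lower and 6 higher of 28, with a median log2 difference of -0.07 and a camera adjusted p of 0.0432 (adjusted p = 0.452 with an estimated correlation). The fatty acid transporter Cd36 was at 1558 ± 165 CPM in WT and 1351 ± 164 CPM in KO, and Acacb, the muscle acetyl-CoA carboxylase, at 390 ± 17.3 and 355 ± 25.1 CPM (SD, n = 3 each). No member was called over all genes or adjusted over the list alone, and the group's call ended without WT replicate 2 (adjusted p = 0.125), KO replicate 1 (0.246) or KO replicate 3 (0.177). Fatty acid oxidation had 18 lower and 8 higher (adjusted p = 0.182). Its member Cpt1a, which acts in fatty acid entry into mitochondria beside Cpt1b of the same list, was at 21.8 ± 0.182 and 18.8 ± 0.512 CPM. Insulin signalling and glucose handling had 20 lower and 10 higher (adjusted p = 0.112); Hk2, the muscle hexokinase, was at 664 ± 30.0 CPM in WT and 562 ± 95.1 CPM in KO, and the insulin receptor gene Insr at 144 ± 3.25 and 126 ± 13.4 CPM. Left-out libraries brought both lists past the threshold as lower: fatty acid oxidation without WT replicate 1 (0.0214) or KO replicate 2 (0.00657), and also with the length correction (0.0409), and insulin signalling without KO replicate 2 (0.017). These values assume the preset correlation of 0.01. Over all libraries the estimated correlation was 0.302 for fatty acid oxidation and -0.001 for insulin signalling. Glycolysis had 13 higher and 2 lower (adjusted p = 0.237).

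The remaining groups did not pass the camera threshold, and none of their members was called over all genes or adjusted over the list alone. Muscle atrophy and growth genes had 8 higher and 13 lower (adjusted p = 0.0879), with the ubiquitin ligase Trim63 at 179 ± 33.5 CPM in WT and 145 ± 17.3 CPM in KO (SD, n = 3 each). Regeneration and denervation genes had an adjusted p of 0.756, the unfolded protein and heat shock response 0.613, the circadian clock 0.391 and immediate early genes 0.237. Inflammatory cytokines and chemokines had 0.391, interferon-stimulated genes 0.446 and the extracellular matrix 0.927. Among markers of other cell types, adipocyte markers were nearest to the threshold, 10 higher and 5 lower with an adjusted p of 0.0765, and erythroid markers had 1 higher and 5 lower with 0.119. Schwann cell and nerve markers had an adjusted p of 0.250, endothelial markers 0.360, smooth muscle and pericyte markers 0.431, satellite cell markers 0.446, fibro-adipogenic and fibroblast markers 0.613 and tenocyte markers 0.937. Several of these groups passed when 1 library was left out, all at the preset correlation of 0.01. The estimated correlation over all libraries was 0.9385 for erythroid, 0.499 for nerve, 0.498 for fibroblast and 0.435 for tenocyte markers. It was 0.482 for interferon-stimulated genes and 0.478 for the matrix. Adipocyte markers had 0.121, immediate early genes 0.049 and atrophy genes 0.0416. Where it is high, the p-values below can be far too small. Without WT replicate 1 nerve (adjusted p = 0.00342) and erythroid markers (0.0119) were lower, and erythroid markers also passed as lower with the length correction (0.0346). Without WT replicate 2 adipocyte markers (0.0379) were higher and the extracellular matrix (0.00351) lower, whereas without WT replicate 3 the matrix (0.000451), adipocyte (0.00385), fibroblast (0.00953) and tenocyte markers (0.0181) were higher and atrophy (0.0181) and immediate early genes (0.0293) lower. Without KO replicate 1 interferon-stimulated genes were lower (0.00599), and without KO replicate 2 they were higher (0.00189) while atrophy genes (0.00189) and erythroid markers (2.63e-09) were lower. Without KO replicate 3 adipocyte markers (0.0197) were higher and nerve markers (0.00105) lower. Lymphocyte, neutrophil and mast cell, skin and hair, and sex-linked check lists had 3, 4, 1 and 4 measured members and were not tested.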

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

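The exact, likelihood ratio and newer quasi-likelihood tests, the removal of 7SK and 7SL rows, the receptor list without Esr1 and the length correction were chosen after seeing the data. No filter beyond 1 read gave 14 genes higher and 5 lower, 3 of them list members, and Esr1 at -1.44 (adjusted p = 0.000142); DESeq2 gave 2 higher and 1 lower, 2 of them list members. The edgeR exact test gave 3 higher and 1 lower, 3 of them list members, with Esr1 at -1.45, and the likelihood ratio test gave 4 higher and 1 lower, 3 of them list members, with Esr1 at -1.45. The cause was not tested. RLE, upper-quartile and no scaling, the stricter filter, limma voom, the newer quasi-likelihood fit and removal of 7SK and 7SL rows gave 0 and 0. Leaving out 1 library gave 0 to 2 genes higher, 0 to 1 lower, 0 to 2 list members and Esr1 from -1.60 to -1.36 (adjusted p 0.0903 to 0.822); calls came only without WT replicate 1. Over all 18 alternatives Esr1 had adjusted p from 4.83e-05 to 0.822 and no change of sign.

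Camera at the preset correlation of 0.01 called 5 to 9 lists higher and 2 to 6 lower when 1 library was left out. With an estimated correlation 0 and 0 passed and by fry 0 and 0. Fry's mixed test, which has no direction, passed 1 list, the receptors and coregulators, which contains Esr1 (adjusted p = 0.00634). After length correction 4 higher and 4 lower passed. The ribosomal list no longer did (mean z from 0.625 to 0.385), nor did the macrophage list, whose adjusted p went from 0.0332 to 0.0505 in the same test as its mean z stayed close, 0.708 and 0.652, so that its lost call says nothing for length; fatty acid oxidation (0.0409) and erythroid markers (0.0346) passed as lower, and the cause was not tested. Of the lists that had not passed, 4 turned and passed in 3 fits: without WT replicate 3 the extracellular matrix (adjusted p = 0.000451) and tenocyte markers (0.0181) were higher, without KO replicate 1 interferon-stimulated genes (0.00599) were lower, and without KO replicate 3 genes of the mitochondrial genome (0.00031) were higher. Over the 6 such fits these lists had adjusted p from 0.000451 to 0.779, 0.0181 to 0.661, 0.00189 to 0.942 and 8.79e-09 to 0.998, in that order. All of these values assume the preset correlation of 0.01. The estimated correlations over all libraries were 0.478, 0.435, 0.482 and 0.885 in the same order, so that the p-values can be far too small. The cause of these turns was not tested.

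The replicate block, fitted because labels number libraries 1 to 3 in each group, left 0 and 0 genes called, Esr1 at -1.45 (adjusted p = 0.182), and 6 lists higher and 4 lower. Same-numbered libraries had correlations of their deviations of -0.015, 0.159 and 0.038, and not every library correlated best with its own number, so the numbers were not taken to pair them. At an adjusted p under 0.01 the authors' deposited table called 4 genes. Esr1 rested on 16 to 50 counts per library, which limits its precision.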

Other observations

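The tests on the myosin paralogs, the overlapping exons, the tissue, the fast-fibre genes and the ribosomal list were chosen after the result was seen. Myh7 of slow fibres took more counts than the 3 fast myosin heavy chains together in all 6 libraries labelled quadriceps, a muscle group known as mostly fast in mice. Reads passed between myosin paralogs are argued against as the whole cause by 7 other slow and fast gene pairs, Tnnc1 with Tnnc2 being left out for missing counts: the slow member was higher in all 6 libraries in 6 pairs by counts and in 5 by counts per exonic base in GENCODE M21, where Tnnt1 lay above Tnnt3 in 1 library and Tnni1 above Tnni2 in 0. Reads lost to overlapping exons are argued against likewise by the 6 pairs with under 10% of their exonic bases overlapped, of which 5 had the slow member higher by counts and 4 per exonic base. Another muscle than the label names, or a slow part of the quadriceps, may account for the profile. These cannot be told apart here, since no reference muscle was analysed. A mean Myh4 share of 1.12% is low for a muscle group known as mostly fast, but does not tell which of these holds.

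Higher fast-fibre transcripts in KO may reflect more type IIB fibre tissue in the KO pieces. A larger IIB share alone would raise no fast gene more than Myh4, the myosin of these fibres. Of 15 fast genes set over Myh4 counts, 1, Actn3, was higher in all KO than in all WT libraries and 1, Myh2, was lower in all, where chance gives 0.75 in each direction. All ratios share the Myh4 counts, which were lowest in WT replicate 2 (1417), where each ratio was the highest of the WT libraries. The mean ratio was lower in KO than in WT for every gene but Actn3 (1.59 times WT) and Pvalb (1.07 times). Most fast genes thus rose less than Myh4 or fell, which a larger IIB share allows. The ratios address type IIB fibres only. The mean Myh1 share, of type IIX fibres, was 9.36% in WT and 12.3% in KO, and a larger IIX share was not tested. No value here decides, so a difference in fibre share stays open, with an effect of the genotype on fibre type untested beside it. No fibre counts bear on this.

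Lists of short, abundant transcripts, the respiratory chain, antioxidant and ribosomal protein genes, were higher in KO, and a gene length bias between libraries could raise such lists together. Corrected for exonic length and abundance, 3 of the 4 lists stayed past an adjusted p of 0.05. These were complex I, complexes II to V and antioxidant defence. In that order their mean z values, signed by direction, were 0.852 ± 0.791, 1.03 ± 0.765 and 0.886 ± 0.934 before correction. After it they were 0.519 ± 0.784, 0.682 ± 0.734 and 0.766 ± 0.938 (SD over genes), so that length may carry part or all of each. Staying past the threshold cannot decide against length as the whole cause, since the test assumed a preset correlation between genes. With that preset and no correction, 4 of 10 splits of the libraries, the real one included, called at least as many lists as the real split. The ribosomal list, whose mean z went from 0.625 ± 0.75 to 0.385 ± 0.727, shifted by no more than complex I and ended at an adjusted p of 0.0868 because it started lower, so that length as its whole cause cannot be told apart from a part. An effect of the genotype stays open for all 4, and none of them passed with an estimated correlation. The fast-twitch list, not among these 4, also held short transcripts, with a median exonic length of 2487.5 bases against 4184 over the genes tested. The same correction moved it from a mean z of 1.37 to 1.15 (adjusted p from 2.75e-06 to 0.000211), so that length may carry part of it too.

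The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 0 genes and the highest of the other splits called 96; with 0 in the real split all 10 of 10 must give as many, so this count says nothing about chance. For gene lists the real split called 8 and the highest other 13, and 4 of 10 splits gave as many. The split with 96 genes set WT replicates 1 and 2 and KO replicate 2 against the rest and points to a structure of the samples apart from genotype, whose source was not tested.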
